A study of Mus musculus with 7 samples.

How the data were processed

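The samples were 7 bulk RNA sequencing libraries from mouse pancreatic tumour organoids, which are small 3-dimensional cultures grown in a gel matrix. The organoids came from KPCY mice (strain C57BL/6), in which Cre expressed in the pancreas switches on a mutant Kras allele, deletes Trp53 and turns on a yellow fluorescent protein (YFP) reporter. Per the labels, the cultures were at passage 8 and were transduced with lentivirus carrying a short hairpin RNA (shRNA) against Usp25 (4 libraries) or against the YFP reporter (3 control libraries). They recovered for 72 hours and were selected with puromycin for 30 hours. Group and replicate number were taken from the sample titles. The labels do not say whether the libraries of a group came from separate cultures or carried the same hairpin, so the p-values measure only the spread between these libraries, which may be technical.

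The unit of the deposited table was signal, here gene read counts that the authors had divided by 1 size factor per library. Trimmomatic 0.36, STAR 2.5.2a, RSEM 1.2.31, DESeq2 1.20.0, R 3.5.1 and the genome build GRCm38 are named, with no role, per the submitters' processing notes. The annotation version, the strand setting and the treatment of reads matching several genes are not given in the sources used here. In each library every value was a whole multiple of 1 step (100% of values within 0.01 of a whole number, largest distance 5.8e-10). Dividing by that step recovered whole numbers, which are called reads here. Whether they are counted reads or rounded estimates is not given in the sources used here. The recovered reads per library ran from 23165775 to 24678379. At the minimum mean of 10 normalized counts, counting error alone is about 31.6% of a value, and this covers counting error only. Every sample column of the table was used.

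Gene symbols and coordinates came from the GENCODE M21 annotation of GRCm38, which matched 51633 of the 51912 gene identifiers. The deposited values were transformed to log2(value + 1). Genes with a mean of at least 10 normalized counts over the 7 libraries (14633 genes) were tested two-sided with limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Groups are given as the mean of the normalized counts ± SD. For Usp25 an exact permutation test of the normalized counts was added.

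A set of 37 gene lists was written before the data were examined, covering HIF-1 and metabolism, stress and signalling pathways, the cell cycle, tumour and duct markers, and markers of other cells a culture can hold. The 36 lists with at least 3 genes tested were compared with all other genes by camera in limma, with a preset correlation between genes of 0.01 and with the trended variance, adjusted over the lists. Members were counted at an adjusted p under 0.05 over all genes tested and adjusted over the list alone. Camera was also run with an estimated correlation. A further 5 lists were written after results had been seen and were adjusted over those 5 alone. They are named as such where used.

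The genes named in the text followed a rule fixed before the data were examined. It took Usp25; the 10 largest rises and 10 largest falls among genes with a mean of at least 50 normalized counts, an adjusted p under 0.05 and no overlap between the groups; up to 4 members with the smallest p from each list; and any member stated not to have passed. Predicted genes, pseudogenes and ribosomal protein copies were passed over in the top 10s, the last as every symbol that starts with Rpl or Rps. Of this kind were 72 rises and 135 falls that met the other conditions, beside 1136 and 1480 that stayed eligible. Genes outside this rule are marked as chosen after their values were seen. Genes with near-identical copies or pseudogenes, whose reads the counting may have divided, are uncertain. They include Gapdh, Ldha, Tpi1, the ribosomal protein genes, Ifit3b, H2-Q4, Ugt1a7c and the Rn7s genes.

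Alternatives fixed beforehand were other pseudocounts (0.5 and 5), no filter, a minimum mean of 50, TMM and quantile scaling, eBayes without a trend or robust, library weights, a replicate block, each library left out, camera on ranks or with an estimated correlation, and fry. Because whole reads could be recovered, edgeR 4.0.16 and DESeq2 1.42.0 were run on them as alternatives, not as the main test. A correction for GC content and transcript length and a glycolysis list without HIF-1 targets were added after the data were examined. Replicate libraries were compared before averaging. The closest pair, control 2 and control 3, still differed by more than sampling noise (chi-square per gene 4.14), so all 7 libraries were counted separately. Control pairs ran from 4.14 to 18.1 and Usp25 shRNA pairs from 24.8 to 56.8, so the Usp25 shRNA libraries were more spread. The main test fits 1 spread per gene to both groups.

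The test was tried on simulated counts for the comparison of 4 Usp25_shRNA with 3 control libraries over 14248 genes. It recovered 44.8% of 67 genes changed by 1.5-fold, 69.7% of 66 changed by 2-fold and 93.8% of 65 changed by 4-fold. Of 143 calls, 6 were false.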

Results

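The deposited table gave normalized read counts for 7 libraries of KPCY mouse pancreatic tumour organoids, 3 transduced with a control shRNA against the YFP reporter and 4 with shRNA against Usp25. Usp25 encodes a deubiquitinase, an enzyme that removes ubiquitin from proteins. The study asked what depends on Usp25 in these tumour cells, with HIF-1 and metabolism named in its title. Depth was even, from 23699889 to 24561735 recovered reads in the controls and from 23165775 to 24678379 in the Usp25 shRNA libraries. Between 20614 and 20713 genes were detected per control and between 21132 and 21402 per Usp25 shRNA library. The first principal component held 50.7% of the variance and placed the controls at -43.6, -33.5 and -37.6. Usp25 shRNA replicates 1 to 4 lay at 24.9, 63.2, 26.3 and 0.387, so that replicate 4 was nearest to the controls and replicate 2 farthest.

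Usp25 itself (ENSMUSG00000022867, GRCm38 chromosome 16, 77013706 to 77116780) was lower in every Usp25 shRNA library. Its level was 2210 ± 82.5 normalized counts in controls (SD, n = 3) and 659 ± 146 after Usp25 shRNA (SD, n = 4), or 29.8% of control. Replicates 1 to 4 kept 26.0%, 32.0%, 38.1% and 23.2% of the control mean. The log2 change was -1.77 (SE 0.16, limma adjusted p = 0.00164). An exact permutation test over the 35 splits of 7 libraries gave p = 0.0571, which is the one-sided share of 1 split, doubled. It is the smallest p that this test can give. By absolute difference, 1 of the 35 splits, the real one, was as large. Shares of splits given elsewhere are by absolute size and not doubled.

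**Figure D1:**
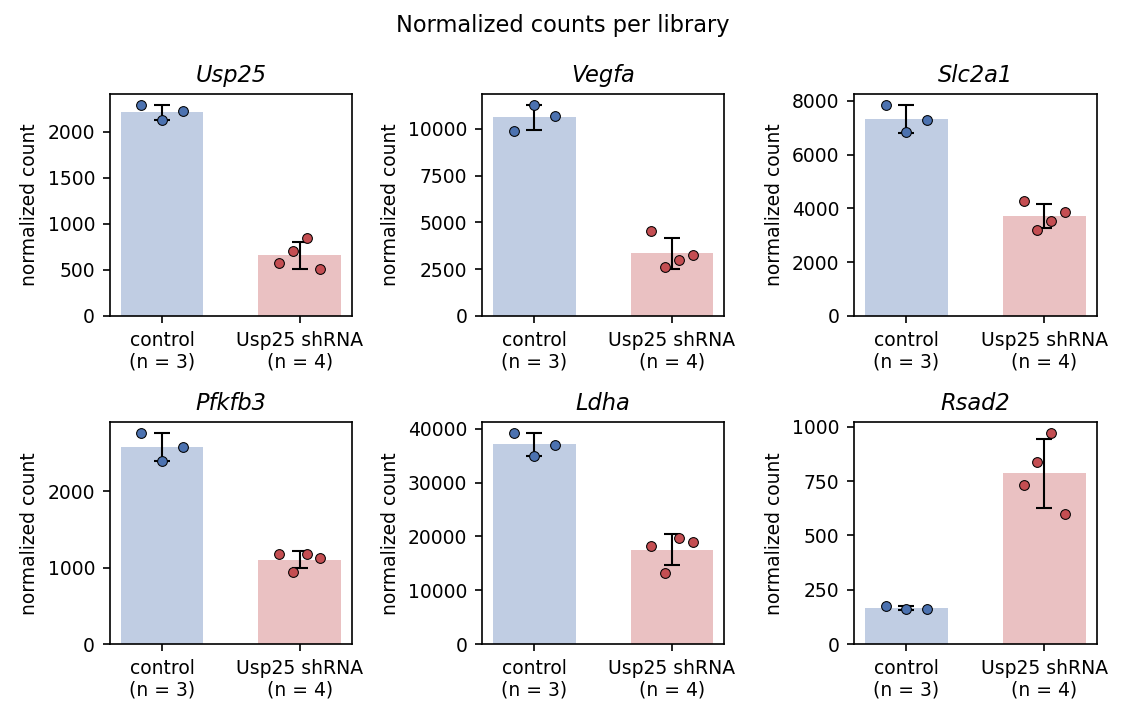
Normalized counts of Usp25, Vegfa, Slc2a1, Pfkfb3, Ldha and Rsad2 in each library (vertical axis, linear from 0), for controls (n = 3) and Usp25 shRNA (n = 4). Points are libraries, bars group means and whiskers SD; every Usp25 shRNA library lies below the controls for the first 5 genes and above them for Rsad2.

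Usp25 shRNA was accompanied by broad change. Of 14633 genes tested, 3177 changed (limma, adjusted p under 0.05), 1448 higher and 1729 lower, and 378 of the higher and 339 of the lower genes moved at least 2-fold. Groups did not overlap for 5580 genes (38.1%, against 5.71% by chance). The share of changed genes that were higher was 45.6%, and it was 57.0% under quantile normalization. The count fell to 1205, 1172 and 581 genes without control 1, 2 or 3, each of which leaves 2 controls. Without a control, the number of members called in the direction of the list also fell by over 1.5 times for 13 of the 17 called gene lists, and those of the HIF-1, glycolysis, fatty acid synthesis and basal-like lists did not.

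Among the genes the naming rule allows (mean of at least 50 normalized counts), the largest rise was in Elovl2. This gene of polyunsaturated fatty acid elongation went from 8.96 ± 3.98 to 110 ± 56.9 normalized counts (log2 change 3.43, SE 0.39, adjusted p = 0.00375). Clip3 rose 8.89-fold. The sterol exporters Abca1 and Abcg1 rose 7.69-fold and 4.75-fold (adjusted p = 0.00375 and 0.00431), and Acsl6, an acyl-CoA synthetase, rose 5.51-fold. Rn7sk, the small nuclear RNA that holds back the elongation factor P-TEFb, rose 5.81-fold. Rgs20, Cfi (complement factor I) and Ugt1a7c rose 5.21-fold, 4.90-fold and 4.77-fold. Cym rose 5.44-fold with an adjusted p of 0.0362; its call ended without control 1, 2 or 3 or Usp25 shRNA replicate 3 (adjusted p = 0.126, 0.0688, 0.0949 and 0.0544), and its rise was 3.38-fold without Usp25 shRNA replicate 1.

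By the same rule the largest fall was in Serpine1, which encodes plasminogen activator inhibitor type 1, from 8823 ± 457 to 1173 ± 823 normalized counts (log2 change -3.26, SE 0.56, adjusted p = 0.00889). The HIF-1 targets Adm (adrenomedullin) and Ndrg1 fell 7.96-fold and 6.62-fold, the latter from 12030 ± 585 to 2025 ± 972. Ptges, the prostaglandin E synthase, fell 7.34-fold. Unc13a, a gene of synaptic vesicle priming, fell 6.56-fold with the smallest adjusted p of these genes, 0.000662. Cyp2s1, Otop1, Kbtbd11, Rnf186 and Klhl3 fell between 6.47-fold and 9.51-fold (limma adjusted p from 0.0108 to 0.0208). Without Usp25 shRNA replicate 2, Cyp2s1, Kbtbd11, Rnf186 and Klhl3 fell less, by 5.52-fold, 5.23-fold, 5.74-fold and 4.16-fold, and stayed called. Calls for Cyp2s1, Otop1, Kbtbd11, Adm and Klhl3 ended when any control was left out, with adjusted p from 0.0532 to 0.0763 and log2 changes of -2.66 or lower.

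HIF-1 is the transcription factor of the response to low oxygen. Of its 39 target genes tested, 38 were lower after Usp25 shRNA and none was higher, with a median log2 change of -1.19 or a 2.28-fold fall. Vegfa, the vascular growth factor, fell from 10612 ± 691 to 3351 ± 833 normalized counts (log2 change -1.69, SE 0.16, adjusted p = 0.00262). Pfkfb3, whose product activates glycolysis, fell by 1.22 on the log2 scale, Gpi1 by 1.25, and Fam162a went from 1969 ± 126 to 707 ± 153 normalized counts. The exception was Pfkfb4 at -0.23 (SE 0.19, adjusted p = 0.399). The count was also 38 adjusted over the list alone. Mean list levels in Usp25 shRNA replicates 1 to 4 were -1.15, -2.10, -1.38 and -1.12 relative to the control mean, and the controls lay between -0.03 and 0.03. Camera gave an adjusted p of 1.21e-22, and the adjusted p was 0.445 with an estimated correlation.

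Glycolysis genes fell with them: 18 of 21 were lower and none higher, also 18 adjusted over the list alone, with a median log2 change of -0.88. Hk1 (hexokinase) fell from 5877 ± 271 to 3450 ± 261 normalized counts, and the glucose transporter gene Slc2a1 from 7336 ± 515 to 3714 ± 456. Gapdh fell by 0.80 on the log2 scale, and Ldha (lactate dehydrogenase) by 1.10. Camera gave an adjusted p of 1.31e-10, with an adjusted p of 0.445 with an estimated correlation. The list shares 11 members with the HIF-1 targets. Among the other 10, a subset formed after the data were examined, 7 fell (camera adjusted p = 0.00157, and adjusted p = 0.285 with an estimated correlation).

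The transcript of Hif1a, the oxygen-regulated subunit, was 4820 ± 149 normalized counts in controls and 5128 ± 602 after Usp25 shRNA (log2 change 0.08, SE 0.10, limma adjusted p = 0.568). Of 12 HIF pathway components, 5 were lower and 1 higher, also adjusted over the list alone, and the list was not called by camera (adjusted p = 0.0802). It was called lower in 5 camera alternatives, with adjusted p from 0.0108 (no filter) to 0.0394 (DESeq2). Egln1, a prolyl hydroxylase that marks HIF for degradation, fell by 1.04 on the log2 scale. Among the lower components, Egln1 and Egln3 (the latter chosen after its values were seen) are also counted among the HIF-1 targets. Arnt, the partner subunit of HIF-1, fell by 0.72, and Epas1, which encodes HIF-2 alpha, by 0.65. Crebbp, a coactivator, was higher by 0.45. Without control 2 or 3, 3 components were called lower and none higher, and the call of Crebbp ended (adjusted p = 0.0548 and 0.0611).

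**Figure D2:**
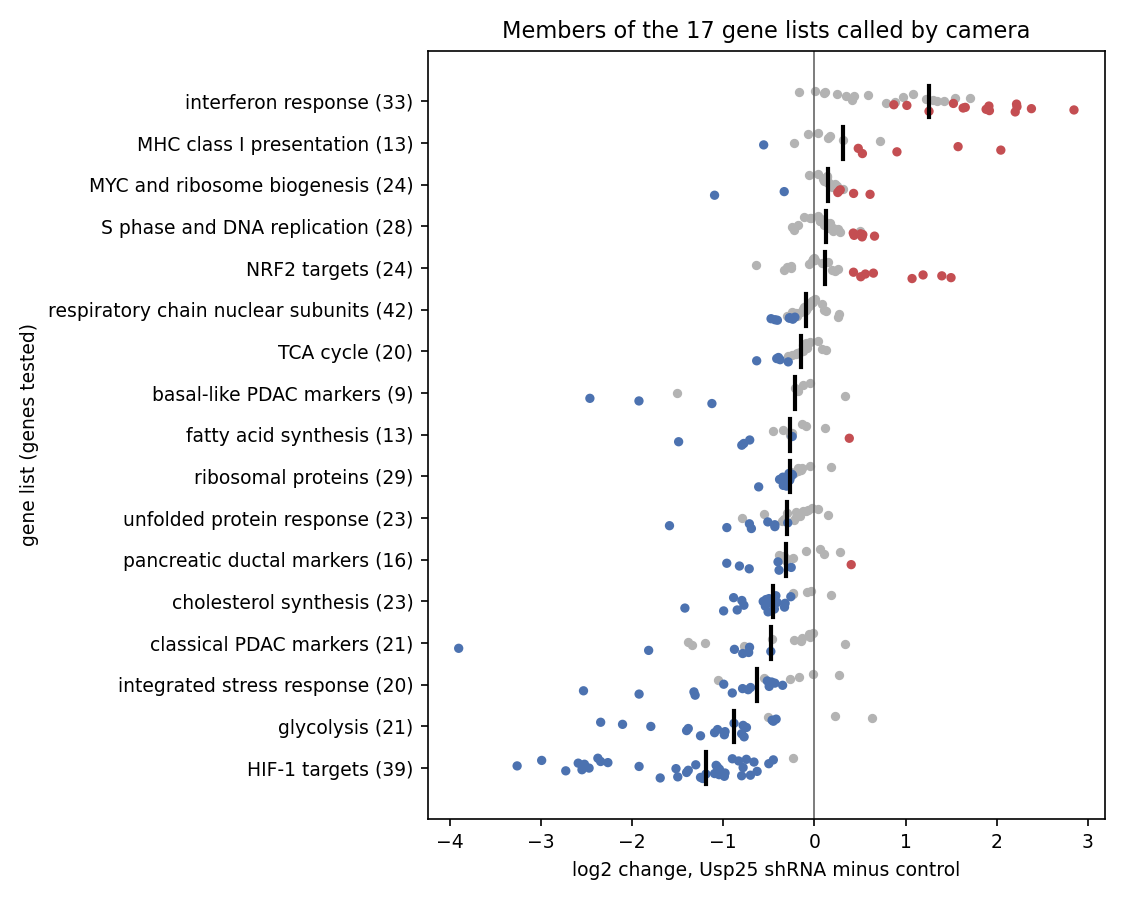
Log2 change (Usp25 shRNA minus control, horizontal axis) of each member of the 17 gene lists called by camera, with genes tested in brackets. Blue and red points are members called lower and higher, grey points are not called and black bars are list medians; 38 of 39 HIF-1 targets are called lower and 14 of 33 interferon genes higher.

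Stress response genes were also lower. In the integrated stress response, the ATF4 programme of amino acid shortage, 14 of 20 genes fell and none rose (18 lower adjusted over the list alone; median log2 change -0.63). Nupr1 went from 5916 ± 765 to 2406 ± 440 normalized counts, Ddit3 (CHOP) fell by 1.92 on the log2 scale and Psat1, an enzyme of serine synthesis, by 0.90. In the unfolded protein response 8 of 23 fell (9 adjusted over the list alone), among them the chaperone gene Hspa5 by 0.96 and Edem1 by 0.69. Camera gave adjusted p of 2.64e-07 and 0.000162 for these lists, and the adjusted p was 0.445 for both with an estimated correlation. Without control 1, 2 or 3, 5, 9 and 3 integrated stress response genes and 3, 3 and 3 unfolded protein response genes were called. Without Usp25 shRNA replicate 3, 5 of the latter were called.

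Lipid synthesis genes fell as well. Of 23 cholesterol synthesis genes, 18 were lower and none higher, with 19 lower and 1 higher adjusted over the list alone (median log2 change -0.45). Insig1, a sterol sensor protein gene, fell from 5081 ± 380 to 2579 ± 482 normalized counts, and Sc5d, a late enzyme of the pathway, fell by 0.51 on the log2 scale. In fatty acid synthesis 5 of 13 genes fell and 1, the synthase gene Fasn (chosen after its values were seen), rose by 0.38 on the log2 scale (9 and 1 adjusted over the list alone), with Scd1, a desaturase gene, down by 0.80 and Acss2, which makes acetyl-CoA from acetate, down by 1.49. Camera gave adjusted p of 9.55e-08 and 0.00348, and the adjusted p was 0.445 for both with an estimated correlation. Without control 1, 2 or 3, 5, 9 and 3 cholesterol genes were called lower. Of the fatty acid list, 8 were called lower without Usp25 shRNA replicate 1, and none higher without control 1, control 3 or Usp25 shRNA replicate 3.

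Interferon response genes were higher. Of 33 tested, 14 rose and none fell (16 higher adjusted over the list alone), with a median log2 change of 1.26. Rsad2 (viperin, an antiviral enzyme) rose from 167 ± 8.92 to 785 ± 160 normalized counts (log2 change 2.20, SE 0.16, adjusted p = 0.000715), Parp14 by 1.26 on the log2 scale and Cmpk2 by 1.92. Ifit3b rose from 3.10 ± 1.07 to 29.8 ± 12.6 normalized counts. The mean list level was 1.15, 0.24, 1.63 and 1.82 in Usp25 shRNA replicates 1 to 4. In controls 1 to 3 it was 0.18, -0.11 and -0.07, so that Usp25 shRNA replicate 2 lay nearest to the controls. Camera gave an adjusted p of 1.52e-08, and 0.445 was the adjusted p with an estimated correlation. Without Usp25 shRNA replicate 2, 27 genes were called higher; without control 2 or 3 the number was 8 or 7.

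Of 13 genes of MHC class I antigen presentation, 5 rose and 1, H2-T23 (chosen after its values were seen), fell (7 and 2 adjusted over the list alone; median log2 change 0.32). Tapbp (tapasin) rose from 1631 ± 34.2 to 2353 ± 122 normalized counts and B2m, the light chain of MHC class I, by 0.48 on the log2 scale. Camera gave an adjusted p of 0.0198, and the adjusted p was 0.445 with an estimated correlation. At a minimum mean of 50 the adjusted p was 0.146, the highest of a range from 0.00487 over the camera alternatives other than the estimated correlation; without control 3, 2 genes were called higher. Leukocyte markers did not rise with these genes. Of 15 markers, 12 lay below the minimum mean, where their control means summed to 16.5 and their Usp25 shRNA means to 15.2 normalized counts. Of the 3 tested, Cd68 fell by 1.40 on the log2 scale (1 lower, also adjusted over the list alone), Cd14 was at -0.50, and Csf1r was at 1.08 (adjusted p = 0.204); the list was not called (adjusted p = 0.45).

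NRF2 targets, genes of the antioxidant response, held 8 higher of 24 and none lower (10 higher adjusted over the list alone; median log2 change 0.12). The glutathione transferase genes Gstm1 and Gsta3 rose 2.10-fold and 2.83-fold. Camera gave an adjusted p of 0.0341, and 0.453 was the adjusted p with an estimated correlation. The call ended without control 2 or Usp25 shRNA replicate 3, at a minimum mean of 50 and on ranks (adjusted p = 0.0788, 0.0801, 0.0518 and 0.0558, with 0.00859 the lowest over the camera alternatives other than the estimated correlation). Without control 1, 2 or 3, 3 genes were called, and without Usp25 shRNA replicate 1 or 3, 5 were.

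Of the replication, mitosis and MYC list genes that changed, more rose than fell. Of 28 S phase and DNA replication genes 6 rose and none fell, also adjusted over the list alone (median log2 change 0.13). The replication helicase gene Mcm2 rose from 2067 ± 338 to 3250 ± 304 normalized counts, and Fen1, a nuclease of replication, by 0.52 on the log2 scale. Among 24 MYC and ribosome biogenesis genes 5 rose and 2 fell (7 and 2 adjusted over the list alone), with Rrp12 higher by 0.61, and Ldha and Myc (the latter chosen after its values were seen) lower by 1.10 and 0.33. Camera called both lists higher (adjusted p = 0.00421 and 0.00339; adjusted p = 0.445 and 0.499 with an estimated correlation). For the latter list adjusted p ran from 0.000266 to 0.0271 over the camera alternatives other than the estimated correlation. Without control 3 these lists held 1 higher gene each, and the MYC list also held 1 without control 1 or 2 or Usp25 shRNA replicate 3, and 3 without replicate 2. G2 and mitosis genes, 3 higher of 26 with 1 adjusted over the list alone, were not called (adjusted p = 0.307). Of these, 4 were called higher without Usp25 shRNA replicate 4 and 1 without each other library in turn.

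Ribosomal protein genes were lower, 19 of 29 with none higher (23 adjusted over the list alone; median log2 change -0.27). Rpl3 fell from 27664 ± 888 to 18179 ± 1856 normalized counts, and Rps18 fell by 0.34 on the log2 scale. RNAs that mostly lack a poly(A) tail, a list written after results had been seen, moved the other way (camera adjusted p = 0.00158, and adjusted p = 0.285 with an estimated correlation). Of 5 tested, Rn7sk and Gm26917 (chosen after its values were seen) were higher, by 2.54 and 1.89, and 4 were higher adjusted over the list alone. The mean level of these RNAs was 1.21, 2.18, 1.07 and 1.08 in Usp25 shRNA replicates 1 to 4. Camera gave the ribosomal proteins an adjusted p of 1.52e-08, with an adjusted p of 0.445 with an estimated correlation. Under quantile normalization 1 ribosomal protein gene was called and the median was -0.12; without control 1, 2 or 3, 12, 1 and 1 were called.

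Of 42 nuclear genes of the respiratory chain 7 fell (5 adjusted over the list alone), including Atp5a1 by 0.41 and Uqcrq by 0.43 on the log2 scale. Of 20 genes of the TCA cycle 5 fell, also adjusted over the list alone, including Suclg2 by 0.63 and Fh1 by 0.29. None was higher in either list. Camera gave adjusted p of 0.0108 and 0.0154, and adjusted p of 0.453 and 0.445 with an estimated correlation. The respiratory chain call ended after the GC and length correction, with quantile normalization and with edgeR (adjusted p = 0.334, 0.135 and 0.0539), and the TCA cycle call with quantile normalization (0.129). The lowest over the camera alternatives other than the estimated correlation were 0.000728 and 0.00094. Without control 1, 2 or 3, limma called 0 genes of either list, against 4 and 4, 7 and 4, 3 and 2, and 8 and 6 lower without Usp25 shRNA replicates 1 to 4 in turn. Of 13 mitochondrially encoded genes 2 were lower, also adjusted over the list alone, and the list was not called (adjusted p = 0.968). Of these, 0 were called lower without control 2 or 3, 1 without control 1 or Usp25 shRNA replicate 3 and 3 without replicate 2. Without replicate 1, 2 were called lower and 2 higher.

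Epithelial and tumour subtype markers were lower where they changed, with 1 exception. Of 16 ductal markers 6 fell and Hnf1b, chosen after its values were seen, rose by 0.40 (8 and 1 adjusted over the list alone); Krt7 went from 50583 ± 3787 to 31369 ± 7314 normalized counts and Epcam fell by 0.25 on the log2 scale. Markers of the classical subtype of pancreatic ductal adenocarcinoma (PDAC) were lower for 7 of 21 (9 lower and 1 higher adjusted over the list alone), with the adhesion gene Ceacam1 down by 1.82 and Erbb3 by 0.79. Basal-like markers were lower for 3 of 9 (4 lower and 1 higher adjusted over the list alone), namely Areg by 1.12, Sprr1a by 1.92 and Ly6d by 2.46. Camera gave adjusted p of 0.0198, 0.00417 and 0.0341, and adjusted p of 0.445, 0.453 and 0.445 with an estimated correlation. Without control 3, 0, 1 and 2 of these markers were called lower, and 10 ductal markers without Usp25 shRNA replicate 4. Without control 1, 2 or 3 no ductal marker was called higher. Without Usp25 shRNA replicate 3 the ductal and basal-like adjusted p were 0.0561 and 0.104, and over the camera alternatives other than the estimated correlation they ran from 0.00162 to 0.148 and from 0.00251 to 0.145, with the classical list from 8.07e-05 to 0.0363.

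Markers of other cells gave no call by camera. Mesenchymal markers held 2 higher, Zeb1 by 2.04 and Zeb2 by 1.61, and 1 lower, S100a4, of 10 tested (adjusted p = 0.468). Fibroblast markers held 1 higher, Pdpn by 0.52, of 4 (adjusted p = 0.468). The call of Pdpn ended without control 1, 2 or 3 and without Usp25 shRNA replicate 1 or 3, that of S100a4 without control 1, 2 or 3, and that of Zeb2 without control 1 or 3. Endothelial markers held Vwf higher by 1.71 and Flt1 lower by 1.41 of 5 (adjusted p = 0.597; median -0.38, mean 0.004, test direction lower), and the call of Vwf ended without control 1 or 2. No acinar marker of 3 changed with limma, over all genes or adjusted over the list alone (list adjusted p = 0.468). Of the endocrine markers only Chga and Syp had enough counts, too few for a list test. Both were higher, Syp from 6.17 ± 2.67 to 39.7 ± 8.33 and Chga from 0.671 ± 1.16 to 19.2 ± 8.83 normalized counts. Genes this low in controls could reach the minimum mean of 10 only if they were higher after Usp25 shRNA, so the filter fixed their direction. Counts adjusted over the list alone were the same for these lists.

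Signalling lists were mixed and not called by camera in the main test. Of 13 Wnt targets 6 fell and 2 rose (7 and 3 adjusted over the list alone; adjusted p = 0.112), with the stem cell receptor gene Lgr5 down by 1.35, Axin2 by 0.59 and Ccnd1 by 0.83. Of 19 ERK output genes 7 fell and 2 rose (8 and 2 adjusted over the list alone; adjusted p = 0.0571), with Egr1 down by 1.16. This list was called lower with no filter, library weights, edgeR and DESeq2, and without control 2 or Usp25 shRNA replicate 1 or 2 (adjusted p = 0.00639, 0.0398, 0.0249, 0.02, 0.0476, 0.0464 and 0.0276). With no filter the Wnt and TGF-beta lists were called too (adjusted p = 0.0389 and 0.0495). TGF-beta targets held 3 lower and 2 higher of 18 (5 and 2 adjusted over the list alone; adjusted p = 0.188), with Serpine1 and Bhlhe40 among the falls. YAP targets held 5 higher and 4 lower of 16 (5 and 7 adjusted over the list alone; adjusted p = 0.871), with Fjx1 higher by 1.40 and F3 lower by 1.03. NF-kB targets held 3 higher and 1 lower of 21 (3 and 2 adjusted over the list alone; adjusted p = 0.24), with Icam1 higher by 0.76. Immediate early and heat shock genes held 6 lower and 2 higher of 20 (7 and 3 adjusted over the list alone; adjusted p = 0.307), with Fos down by 1.19. These counts depended on the libraries. Without control 3 the members called lower were 1 Wnt, 2 ERK, 3 TGF-beta, 0 YAP, 0 NF-kB and 2 immediate early genes, and those called higher 0, 0, 0, 1, 1 and 1. Without Usp25 shRNA replicate 4 they were 7, 8, 6, 7, 4 and 6 lower and 3, 2, 3, 5, 3 and 2 higher. No NF-kB target was called lower when any library but replicate 4 was left out.

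The p53 targets held 3 lower and 2 higher of 17 (4 and 2 adjusted over the list alone; adjusted p = 0.442), and apoptosis regulators 5 lower and 2 higher of 18 (7 and 2 adjusted over the list alone; adjusted p = 0.295). Autophagy and lysosome genes held 2 lower, Atg9b and Wipi1, and 1 higher, Ulk1, of 23, also adjusted over the list alone (adjusted p = 0.685; median -0.0064, mean -0.05, test direction higher). No histone gene of 6 was called by limma, over all genes or adjusted over the list alone (list adjusted p = 0.45). Of 12 proteins related to USP25 by family or known function, the paralog Usp28 fell by 0.49 and Usp10 rose by 0.26, also adjusted over the list alone (list adjusted p = 0.984). Without control 3, no p53 target, apoptosis regulator, autophagy gene or gene of the last list was called by limma. Without Usp25 shRNA replicate 1 or 3, 2 apoptosis regulators were called lower and none higher. Without replicate 1, 2 histone genes were called lower, and without replicate 4, 3 genes of the last list were called higher. The calls of Usp28 and Usp10 ended without control 1, 2 or 3, and that of Usp10 also without replicate 3.

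**Figure D3:**
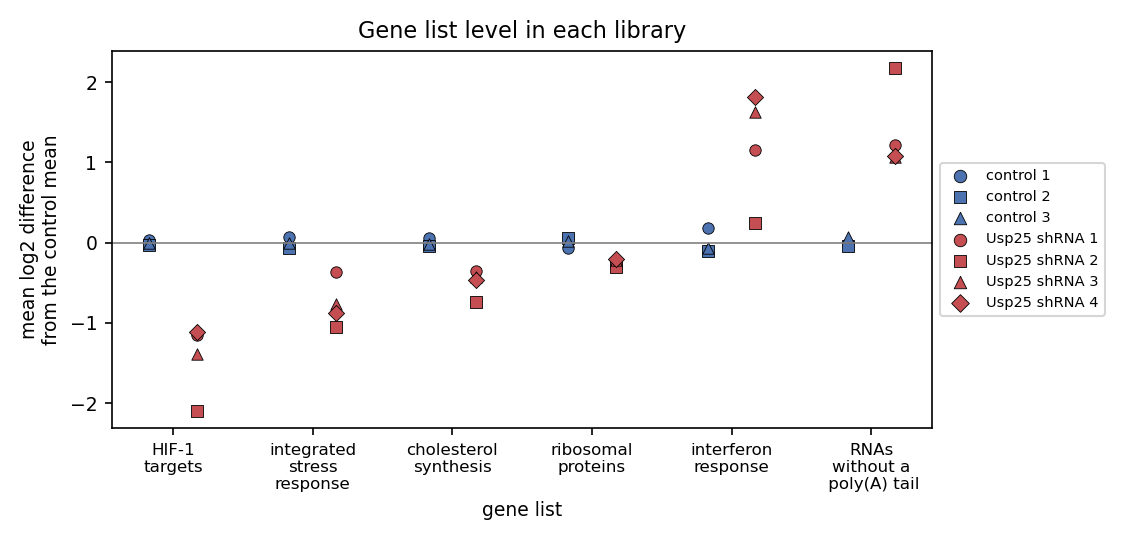
Mean log2 difference from the control mean (vertical axis) of 6 gene lists in each library, controls in blue and Usp25 shRNA in red, with a marker shape per replicate. HIF-1 targets lie between -2.10 and -1.12 in the Usp25 shRNA libraries, and interferon genes between 0.24 in replicate 2 and 1.82 in replicate 4.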

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

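The tests of a single deciding library, of leukocytes and of the hairpin, and the list of RNAs without a poly(A) tail, were chosen after the results they bear on had been seen. Each of the following values had 1 Usp25 shRNA library far from the other 3, with the gap divided by the range of the 4 libraries as the measure. It was above the 95% critical value of Dixon's test for 8 of 195 values (4.1%), and chance gives about 1 in 20. Replicate 2 stood apart for Acsl6 (0.909, log2 level 9.27 against 8.02 to 8.13), Rgs20 (0.844), Dst (0.883) and the TCA cycle list (0.844, mean -0.30). Replicate 1 stood apart for Cym (0.956, 9.13 against 6.33 to 6.45) and, by a small step, Dusp4 (0.898, 10.55 against 10.64 to 10.65). Replicate 4 stood apart for Acta2 (0.878) and the basal-like list (0.905, mean -0.40 against -0.97 to -0.91).

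The fall of the HIF-1 target genes was weighed first. The tables argue against GC content or gene length as the whole cause, since the median log2 change was -1.24 after that correction. They argue against a single library, as the median nearest 0 was -1.10 when each was left out, and against a few abundant genes taking the counts, as it was -1.13 under quantile scaling. Of the 35 splits of the 7 libraries, 1, the real one, gave a median as far from 0 (1.19, next 0.98). This argues against chance in how the libraries divide. It is the smallest share that 35 splits can give, so chance is not excluded. The splits do not reach differences between cultures, as libraries of a group may share one. RNAs without a poly(A) tail were highest in replicate 2 (2.18 against 1.07 to 1.21), where the HIF-1 targets were lowest (-2.10 against -1.38 to -1.12). The glycolysis, cholesterol synthesis and fatty acid synthesis lists were also lowest in replicate 2 (mean levels -1.34, -0.74 and -0.58). So were the integrated stress response and unfolded protein response lists (-1.05 and -0.55). This match rests on replicate 2. Replicate 3 had the lowest level of RNAs without a poly(A) tail among the Usp25 shRNA libraries (1.07), yet its HIF-1 fall (-1.38) was larger than those of replicates 1 and 4. Uneven poly(A) selection or RNA quality was not tested for any of these falls and stays open. A biological response to Usp25 shRNA is a hypothesis that also stays open, and a response to the hairpin sequence itself was not separated from it. The HIF-1 fall did not follow the degree of knockdown. Replicates 4 and 1 kept the least Usp25 (23.2% and 26.0% of control) and had the smallest falls (-1.12 and -1.15). Replicates 2 and 3 kept 32.0% and 38.1% and had the largest (-2.10 and -1.38). With 4 libraries this relation was not tested.

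The rise of the interferon response genes was weighed next. Leukocytes in the cultures are argued against: the tested markers had a median log2 change of -0.50, and the other 12 had group means of at most 5.49 normalized counts, with Lyz2 and Tyrobp at 0 reads. GC content or length is argued against as the whole cause, with a median of 1.199 after correction. A response to the hairpin rather than to loss of Usp25 cannot be told apart from the rest, because the labels do not give the hairpin of each library. The mean level was above the highest control in 4 of 4 Usp25 shRNA libraries, but in replicate 2 by little (0.24 against 0.18).

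The fall of ribosomal protein genes together with the rise of RNAs without a poly(A) tail was the third. After the GC and length correction the median log2 change of the ribosomal proteins was -0.18, and under quantile scaling it was -0.12. Both lie between the bounds of -0.1 and -0.2, which were written before these tests but after results had been seen. GC content or length and the scaling of the libraries therefore cannot be told apart from a change in the cells. Uneven poly(A) selection was not tested.

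Across all genes, 1 of the 35 splits, the real one, gave as many changed genes (3177, next 1522). This argues against chance in how the libraries divide for that count. The smallest share that 35 splits can give does not exclude it. The next split set Usp25 shRNA replicates 1, 2 and 3 against the controls with replicate 4, which keeps the controls together. For the number of gene lists called, 2 of 35 splits gave as many (17, highest other 17, the same next split), so chance cannot be excluded. Every other split, each of which mixes the groups, also called lists, from 3 to 17. With controls 1 and 2 and Usp25 shRNA replicate 1 set against the rest, 14 lists were called and 0 genes changed. A list call by camera with the preset correlation therefore does not by itself mark the real groups.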

How the results depend on the processing

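The GC and length correction and the glycolysis list without HIF-1 targets were chosen after the results had been seen. Usp25 stayed lower and past the threshold under all 20 alternatives, with log2 changes from -1.90 to -1.66. Library weights gave 5839 changed genes, with control 3 at the highest weight, 10.8. Leaving out 1 library gave from 581 (without control 3) to 4013 (without Usp25 shRNA replicate 4) changed genes, with 1205 and 1172 without control 1 and 2; fewer samples were then tested. Other settings gave between 2270 (eBayes without a trend) and 4003 (DESeq2) genes, with 3104 for edgeR and 2514 with no filter. Of the 158 named genes other than Usp25, 20 lost their call without a trend, 13 under quantile normalization and 9 with no filter. Leaving out control 1, 2 or 3 ended 48, 48 and 68 of these calls. Quantile normalization moved the split to 1842 higher and 1387 lower, and the cause was not tested.

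With an estimated correlation camera called 0 lists at an adjusted p under 0.05, against 17 with the preset one, and the HIF-1 and glycolysis lists had an adjusted p of 0.445 each. Why the estimate ended these calls was not tested. A simulated list of 30 genes changed by 1.5-fold was called by camera with it (adjusted p = 0.000548). Its genes were drawn independently, so it cannot show how the estimate treats lists whose members move together. Fry asks whether the members of a list move on balance in one direction, without comparing them with other genes, so its 20 calls answer another question than camera. The NRF2, MYC and classical lists missed it (adjusted p = 0.075, 0.0791 and 0.076). Under all other alternatives both stayed lower and past the threshold. Camera has no robust option, so the robust fit adds nothing on lists. The direction of lists that were not called turned in places, where the cause was not tested. Adjusted p were then 0.739 for histone genes (no filter), 0.844, 0.979, 0.996 and 0.876 for YAP targets (minimum mean 50, quantile, edgeR, DESeq2) and 0.359 for mitochondrially encoded genes (quantile). For USP25 related proteins they were 0.899, 0.978, 0.53, 0.928 and 0.927 (minimum mean 50, TMM, quantile, weights, DESeq2). Leaving out 1 library gave ranges of 0.671 to 0.948 (YAP), 0.212 to 0.984 (mitochondrially encoded) and 0.816 to 0.952 (USP25 related). Acta2, at log2 0.03 and not called, was at -0.013 (pseudocount 5), -0.076 (edgeR), -0.09 (DESeq2) and -0.53 to 0.75 with 1 library left out. The fall of mt-Co1, the gene with the most counts, became 0 under quantile normalization, which ties the top gene by construction.

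Whether the replicate numbers pair the libraries was not settled. Deviations of same-numbered libraries correlated at -0.022, 0.21 and 0.025. Controls 1, 2 and 3 correlated best with Usp25 shRNA replicates 4, 2 and 3. The main test used no pairing, as the labels do not say that the numbers mark a shared day. Of the 3 correlations, 2 were under 0.1. A replicate block gave 3718 changed genes (2702 of them among the 3177) and 17 lists, with Acta2 at -0.45 and adjusted p of 0.808 and 0.885 for the mitochondrially encoded and USP25 related lists. Usp25 shRNA replicate 4 has no control of the same number, so the block fit drew the change from replicates 1 to 3 alone. Its HIF-1 median log2 change, -1.23, equalled that of the fit without replicate 4. In simulated data over 14248 genes 44.8% of 67 genes changed by 1.5-fold were recovered, so small changes can be missed. Few genes were changed there and both groups had the same spread. This share therefore need not hold for the real comparison, where 21.7% of the tested genes changed.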

Other observations

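The REST test and the lists of REST-repressed genes, other LXR targets, and interferon ligands and receptors were chosen after results had been seen. So were the genes named below, except Unc13a, Abca1 and Abcg1, which the naming rule gave, and Chga and Syp, members of an endocrine list fixed beforehand. Chga, a granule protein gene, had 2 reads in the 3 controls together and 80 in the 4 Usp25 shRNA libraries. Syp, a synaptic vesicle gene, had 18 and 165. Both passed the minimum mean only through the Usp25 shRNA libraries. The motor protein gene Kif5c lay between 52.9 and 73.5 normalized counts in controls and between 197 and 342 after Usp25 shRNA. Dcx went from 39.9 to 50.8 up to 95.6 to 240, and Gprin1 from 29.1 to 37.8 up to 111 to 233. In contrast Unc13a lay between 690 and 901 in controls and between 96.4 and 162 after Usp25 shRNA, and Grin1, a glutamate receptor gene, between 360 and 407 and between 34.4 and 101.

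The sterol genes moved in opposite directions. Beside lower cholesterol synthesis genes and higher Abca1 and Abcg1, Mylip, which marks the LDL receptor for degradation, lay between 70.6 and 82.6 normalized counts in controls and between 142 and 273 after Usp25 shRNA. Apoe lay between 26.3 and 45.3 in controls and between 66.3 and 110 after Usp25 shRNA. No reads of Ifnl2 or Ifnl3 were counted in any library, and Ifnb1 had 0 reads in the controls and 2 in the Usp25 shRNA libraries, which is below the 3 counts that a count of 0 allows. Of 6 interferon receptor genes tested, 1 (Ifnar1, by 0.44 on the log2 scale) fell and none rose. Camera in limma gave the list of ligands and receptors an adjusted p = 0.187 (0.112 unadjusted).

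A candidate explanation for the rise of Kif5c, Dcx and Gprin1 is loss of repression by REST, which silences such genes outside neurons. Of 17 genes known as REST-repressed and tested, 5 rose and 3 fell, with a median log2 change of 0.33. Camera in limma gave the list a p of 0.19, before and after adjustment. The bound written for this test, a camera p of at least 0.05, was met. A p above the threshold does not exclude a change, and members went both ways, so the test leaves the hypothesis open. The list includes Chga, Syp, Unc13a and Grin1, seen before it was written.

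A candidate explanation for lower cholesterol synthesis with higher Abca1 and Abcg1 is activation of LXR, the oxysterol receptor. Of 7 other LXR targets tested, 2 rose (Mylip and Apoe) and 1 fell (Lpcat3, by 0.43 on the log2 scale), with a median log2 change of 0.30. Camera in limma gave the list an adjusted p = 0.19 (0.182 unadjusted). The bound against LXR was written before its test but after results had been seen. This bound, no call and at most 2 members higher, was met exactly at its limit and not beyond it. The bound in favour, over 5 of only 7 tested, was hard to reach. The test was therefore taken to leave LXR open.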
